A study of Mus musculus with 33 samples.

How the data were processed

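Gene expression was measured on 33 Affymetrix 3′ expression arrays, one for each of 3 cultures of 11 mouse pluripotent cell lines. Per the labels, RNA was extracted with Trizol, amplified and labelled with biotin by a 3′ IVT Express kit, and hybridised to 1-colour arrays. All lines were grown on irradiated mouse embryonic fibroblasts in medium with LIF, a cytokine that keeps mouse pluripotent cells undifferentiated. The deposited table holds 1 intensity for each of 45101 probe sets on each array, on a linear scale. Per the submitters' processing notes, the authors made these values with MAS5, whose version is not given in the sources used here. MAS5 combines perfect-match and mismatch probes into 1 signal and scales each array as a whole. In the deposited table the mean signal after trimming 2% at each end was 500 on every array, so differences in total RNA between arrays cannot be seen. No scanner files or detection calls were used here, and the settings of MAS5 beyond the scaling are not given in the sources used here.

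Groups were taken from the labels: 4 iPSC lines, 4 iPSC-nt-ESC lines, 2 ntESC lines and 1 ESC line, with 3 cultures each. Cultures of 1 line share its clonal history, so the line was the replicate in comparisons of cell types, and the mean of its 3 cultures was its value. The ESC type has 1 line, which was assumed to vary like lines of the other types. In tests among lines of a type the culture was the replicate, and those p-values measure only the spread between cultures of a line. No pair of arrays shared over 0.0532% identical values, so no array was treated as a duplicate. The names of the arrays carry a prefix that is the same for all 12 iPSC-nt-ESC arrays and another for the rest. Prefix and type therefore cannot be told apart in any comparison with iPSC-nt-ESC lines.

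Signals were analysed as log2(signal + 11.36), where the offset is the 20th percentile of the whole table. Folds are on this scale, which understates changes of dim genes. The 64 control probe sets were left out of all tests. A probe set was kept if its signal lay above its own array's median in all 3 cultures of at least 1 line, which left 24423. Gene names came from the platform's annotation of 2016, which gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211. Of the probe sets with 1 symbol, 34754 matched a gene of the mouse RefSeq table for GRCm38.p6 by gene identifier and 204 did not. That table was used for current symbols and for the chromosome of each gene. Each gene was represented by its probe set with the highest mean over all arrays among those with 1 symbol, which gave 12080 genes, 5571 of them with several probe sets past the filter. Probe sets of families of near-identical genes, such as Tcstv1 and Tcstv3, Gbp2 and Gbp2b, and the Pramel and Usp17l genes, can bind more than 1 member, so their assignment is uncertain.

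Types were compared with limma 3.58.1 in R 4.3.3. All 11 line means entered 1 linear model with 4 type means, with empirical Bayes moderation and Benjamini-Hochberg adjustment over the 12080 genes at 0.05. Every adjusted p of a gene is from limma. Lines of 1 type were compared with limma's moderated F test on the arrays of that type. Lists of 540 genes in 20 groups, of which 426 were tested, covered the reprogramming factors, pluripotency, imprinting, fibroblasts, the germ layers, trophoblast, germ line, the 2-cell-like state, chromatin, stress, metabolism, cell cycle, interferon and sex chromosomes. Lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison, and again with the correlation estimated from the data. With the estimated correlation none of the 21 list calls held, so 0 remained. Fry gave 35 calls, but it asks whether a list changed at all, while camera sets a list against the other genes. The counts of fry and camera therefore answer different questions. Relations of lines were tested by exact permutation. Figures were drawn with Python 3.11 and matplotlib 3.10.9.

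The genes named per comparison were the 10 largest changes in each direction among called genes whose line values did not overlap between the types, up to 4 members of each list with the largest absolute change, and 16 genes fixed by name. In tests among lines they were the 10 genes with the largest range. Genes with only a predicted or clone symbol were passed over, and the text prints part of the list members and of the genes fixed by name. The groups, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. The tests of called genes per chromosome, the medians in parts of chromosomes 8 and 11, the fits without chromosomes 8, 11 or Y, and the parent and daughter test without the pair of line 3 were added after seeing the data.

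Line numbers pair each iPSC-nt-ESC line with the iPSC line it was derived from, per the labels. Across genes, the deviations of the 4 such pairs from their type means had correlations of 0.01, -0.11, -0.29 and 0.32. The fit with the line number as a block held only the iPSC-nt-ESC and iPSC lines. It was an alternative chosen before the data were examined, and its value is given where it changes a call. Other alternatives were no offset or 4 times the offset, quantile normalisation, no filter or a filter at the 75th percentile, other uses of probe sets, arrays as units with the line as a random block or as independent replicates, fits of the types compared alone, and each line or culture left out.

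The limma fits were checked on simulated data, with 100 genes changed by 1 and 100 by 2 log2 units among 12080, raised and lowered in turn. The fit recovered 71% and 99% for iPSC against ntESC lines with 6 false calls, and 84% and 100% for iPSC-nt-ESC against iPSC lines with 5. It recovered 71% and 98% for iPSC-nt-ESC against ntESC lines with 8 false calls, and 55% and 92% for iPSC against ESC with 7. For ntESC against ESC it recovered 49% and 88% with 9 false calls, and for iPSC-nt-ESC against ESC 57% and 90% with 6. Among lines it recovered 85% and 98% for iPSC with 12 false calls, 85% and 97% for iPSC-nt-ESC with 14, and 75% and 96% for ntESC with 10. In these checks among lines only 1 line was changed, and only the spread between cultures was simulated. In all checks genes were drawn independently from normal distributions. Between types each gene had the same spread between lines in every type, ESC included. In the data the median SD between line means was 0.195 for iPSC-nt-ESC and 0.1 for ntESC lines. The recovered shares and false calls therefore hold for the simulated setting only. Intensities carry no read depth, and the number of arrays and lines limits the precision.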

Results

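Expression was profiled in 11 mouse pluripotent cell lines with 3 cultures each. The 4 induced pluripotent stem cell (iPSC) lines came from embryonic fibroblasts with doxycycline-inducible Oct4, Sox2, Klf4 and c-Myc. The 2 ntESC lines were embryonic stem cell lines made by transferring nuclei of the same kind of fibroblast into oocytes. Each of the 4 iPSC-nt-ESC lines came from nuclear transfer of the iPSC line with its number, so these cells passed through both kinds of reprogramming. The ESC line was E14, an established 129sv/Jae line from embryos, while all other lines were of mixed C57BL/6 and 129sv/Jae background. All lines were labelled male. Median signal averaged 66.58 ± 2.46 (SD, n = 4 lines) in iPSC, 69.21 ± 3.35 (n = 4) in iPSC-nt-ESC and 62.06 ± 1.28 (n = 2) in ntESC lines, and 73.57 in the ESC line. Over single arrays it ranged from 59.81 to 76.72.

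Cultures of a line correlated at 0.9836 to 0.9925 across genes, and their SD had a median of 0.143 on the log2 scale. Between line means the median SD was 0.135 for iPSC, 0.195 for iPSC-nt-ESC and 0.1 for ntESC lines. Control probe sets set the iPSC-nt-ESC arrays apart from all others. The 18S ribosomal RNA control averaged 611.2 ± 244 (SD, n = 4 lines) there, at least 16.9-fold below each other type, for example 14460 ± 1750 (n = 4) in iPSC lines. The transferrin receptor control averaged 2403 ± 329 (n = 4), at least 6.64-fold above each other type, for example 336.5 ± 50.1 (n = 4) in iPSC lines. The spiked-in bioD transcript was also brighter, at 8292 ± 478 (n = 4) against 5499 ± 119 (n = 4) in iPSC lines. The ratio of 3′ to 5′ Actb signal, which follows RNA quality and labelling, was lower, at 1.282 ± 0.031 (n = 4) against 1.499 ± 0.0335 (n = 4) in iPSC lines, with array ranges of 1.23 to 1.36 and 1.44 to 1.55. These arrays share a name prefix of their own.

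**Figure D1:**
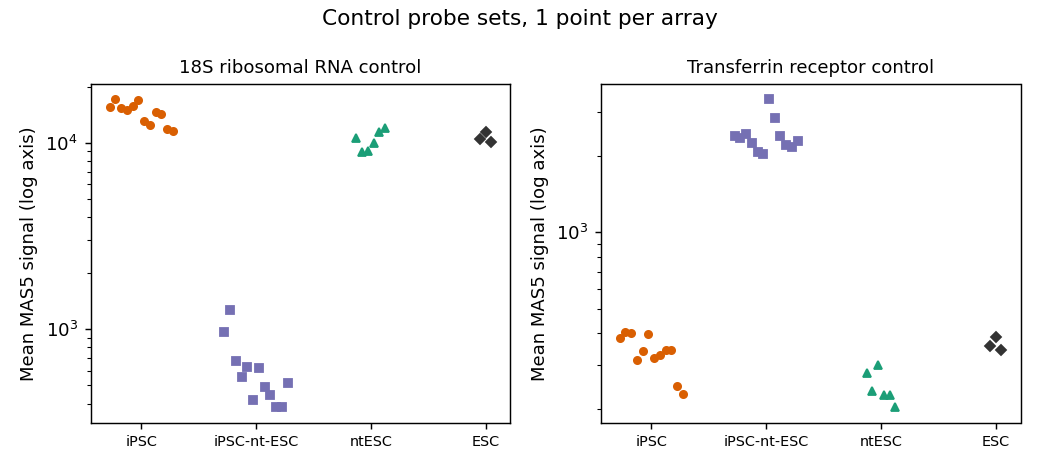
Mean MAS5 signal of the 18S ribosomal RNA and transferrin receptor control probe sets on each of the 33 arrays (log axes), 1 point per array, by cell type. The 12 iPSC-nt-ESC arrays lie between 381 and 1262 for 18S and between 2034 and 3364 for the transferrin receptor, apart from every other array.

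The comparison of iPSC with ntESC lines asks whether pluripotent lines from the same kind of fibroblast differ with the route, defined factors or an oocyte. The Y-linked Eif2s3y, a subunit of a translation initiation factor, changed most: it averaged 5.78 ± 0.92 log2 units (SD, n = 4 lines) in iPSC and 11.70 ± 0.14 (n = 2) in ntESC lines. It was 60.4-fold lower in iPSC lines (log2 change -5.92, SE 0.45, adjusted p = 0.00028). The Y-linked Uty, a relative of a histone demethylase, was 13.4-fold lower (adjusted p = 3.1e-05), and Uba1y, a ubiquitin-activating enzyme, 14.8-fold lower (adjusted p = 0.00028). Scml2, an X-linked Polycomb-group gene of the male germ line, averaged 11.16 ± 0.12 (n = 4) against 7.22 ± 0.47 (n = 2), a 15.3-fold increase (SE 0.39, adjusted p = 0.0011). The core factors did not pass the test: Pou5f1, the gene of Oct4, changed by -0.19 (SE 0.12, adjusted p = 0.34) and Nanog by -0.08 (SE 0.18, adjusted p = 0.8).

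Among the other genes higher in iPSC lines, Nxf3 of the RNA export factor family rose 9.19-fold (adjusted p = 0.0027) and Ipp, transcribed from a retroviral element promoter, 8.02-fold (adjusted p = 0.00028). The laminin chain Lama3 rose 4.66-fold, the homocysteine methyltransferase Bhmt 4.48-fold, the cytochrome c oxidase subunit Cox7b2 4.29-fold, the keratin Krt23 4.2-fold and Ccdc172 4.05-fold. Brdt, a bromodomain protein of the testis, and Tbx21, the T-cell factor T-bet, each rose 3.93-fold. Another probe set of Brdt changed by 0.49 log2 units and did not pass (adjusted p = 0.33). Lower genes included Spry4, a feedback inhibitor of FGF signalling (5.09-fold, adjusted p = 0.046), the PRAME-family gene Pramel18 (4.44-fold, adjusted p = 0.0048), Speer4cos (3.16-fold), Ccser1 (3.11-fold), Zfp352 (3.08-fold), Ubtfl1 (3-fold) and the deubiquitinase gene Usp17la (2.93-fold). For each gene above that was called, all 4 iPSC lines lay on one side of both ntESC lines. The rule for naming the largest changes required this, and it held for every gene called in this comparison.

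The germ line list moved up in iPSC lines (camera adjusted p = 4.2e-05; adjusted p = 0.4 with an estimated correlation). Of its 24 tested genes 6 rose, none fell and 18 did not pass (10 rose adjusted over the list alone), among them Brdt, the homeobox gene Rhox5 (1.57 log2 units, SE 0.27, adjusted p = 0.01) and the synaptonemal complex gene Sycp1 (1.43, SE 0.36, adjusted p = 0.04). Genes of the 2-cell-like state moved down (camera adjusted p = 0.014; adjusted p = 0.54 with an estimated correlation): 6 of 12 fell and none rose, with 8 falling and 2 rising adjusted over the list alone. Zfp352 and Usp17la, both active in early embryos, were among them. Fibroblast markers, which can come from donor or feeder cells, also moved down (camera adjusted p = 9.7e-05; adjusted p = 0.54 with an estimated correlation). Of 41 markers 7 fell and 1 rose, with 12 and 2 adjusted over the list alone. The one that rose was the growth factor receptor Pdgfra (0.9, adjusted p = 0.028), and Prrx1 changed by -0.91 (adjusted p = 0.085). The sex chromosome list moved down (camera adjusted p = 3.3e-05; adjusted p = 0.095 with an estimated correlation), with 2 of 3 genes past the test and 3 adjusted over the list alone. Xist changed by -0.36 (adjusted p = 0.11).

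Among imprinted genes outside the Dlk1-Dio3 region, 3 rose, 1 fell and 31 did not pass of 35 tested (6 and 1 adjusted over the list alone; camera adjusted p = 0.17). Xlr4c rose by 1.47 (adjusted p = 0.044) and Nap1l5 by 1.08 (adjusted p = 0.018), while Phlda2, which restrains placental growth, fell by 1.29 (adjusted p = 0.011). Within the Dlk1-Dio3 region none of 4 genes passed over all genes by its main probe set and 3 rose adjusted over the list alone. Its maternally expressed Rian changed by 0.79 (SE 0.22, adjusted p = 0.054) and Meg3 by 0.51 (SE 0.16, adjusted p = 0.084), while another probe set of Rian rose by 1.36 (adjusted p = 0.027). The orphan receptor gene Nr0b1 fell by 1.16 (adjusted p = 0.025), while the cell cycle inhibitor gene Cdkn2a rose by 1.28 (adjusted p = 0.012). Suz12 of Polycomb repressive complex 2 (0.89, adjusted p = 0.0033) and the mitotic kinase gene Aurkb (0.84, adjusted p = 0.026) rose and both lie on chromosome 11. The reprogramming factors Klf4 (0.31, adjusted p = 0.43), Sox2 (0.22, adjusted p = 0.39) and Myc (-1.16, SE 0.6, adjusted p = 0.25) did not pass.

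In all, 856 of 12080 genes (7.09%) differed, 580 higher and 276 lower in iPSC lines, and 134 and 49 of them by at least 2-fold. In limma 3076 genes had an unadjusted p under 0.05. The count moved to 330 without iPSC-1, 281 without iPSC-2, 167 without ntESC-1 and 199 without ntESC-2, and to 417 without genes of chromosomes 11 and Y (226 higher and 191 lower). Single lines left out ended the calls of Cox7b2, Tbx21, Spry4, Speer4cos, Ccser1, Zfp352, Ubtfl1, Usp17la, Nr0b1, Aurkb, Rhox5, Sycp1, Pdgfra, Xlr4c, Phlda2, Nap1l5 and Cdkn2a, quantile normalisation ended those of Sycp1 and Xlr4c, and the call of the 2-cell-like list ended without iPSC-nt-ESC-3, which shares the fit.

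**Figure D2:**
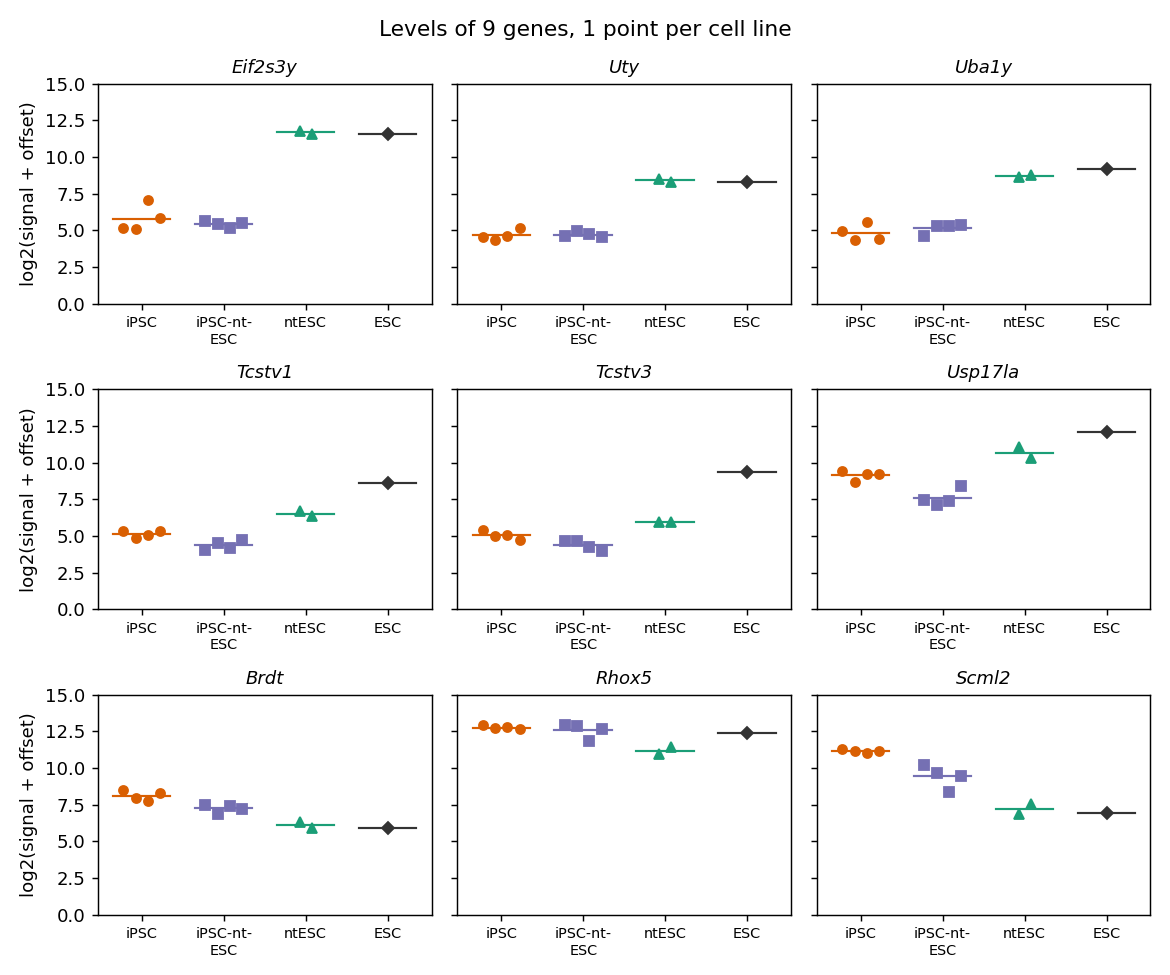
Mean log2(signal + offset) of 9 genes, 1 point per cell line (mean of 3 cultures), with a bar at the mean of each type. The Y-linked Eif2s3y, Uty and Uba1y lie low in all iPSC and iPSC-nt-ESC lines, the early embryo genes Tcstv1, Tcstv3 and Usp17la are highest in the ESC line, and the germ line genes Brdt, Rhox5 and Scml2 are lower in ntESC than in iPSC lines.

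Many of the genes higher in iPSC than in ntESC lines lay on chromosome 11. Its 1058 tested genes had a median change of 0.41 log2 units against -0.03 on other chromosomes, and 91.9% of them were higher against 45.7% elsewhere. They made up 277 of the 580 genes called higher (47.8%) and 1 of those called lower (Fisher's exact test, adjusted p = 1.2e-143 over 120 tests in each direction, chosen after seeing the data). These tests treat genes as independent, although genes of 1 chromosome can move together in a line. Their p-values therefore do not measure the spread between lines. Chromosome X was also enriched among genes called higher, with 38 of its 401 genes (adjusted p = 0.00072), while its median change was -0.04. Chromosome 11 stood out against ntESC lines in iPSC-nt-ESC lines (median 0.32 against -0.13; 419 called higher and 63 lower; adjusted p = 2.8e-98). Against ESC it was higher in iPSC lines (0.37 against -0.04; 131 higher and 8 lower; adjusted p = 3.3e-59) and in iPSC-nt-ESC lines (0.25 against -0.16; 288 and 58; adjusted p = 4e-79). Between iPSC-nt-ESC and iPSC lines the medians were -0.09 and -0.11, and called higher genes were not concentrated there (adjusted p = 0.47). Relative to the median of all lines, chromosome 11 stood at 0.122, 0.094, 0.042 and 0.081 in the 4 iPSC lines, at 0, 0, 0.085 and 0 in the iPSC-nt-ESC lines, at -0.261 and -0.262 in the ntESC lines and at -0.181 in the ESC line. Chromosome 8, with 643 tested genes, was higher in the ESC line alone, by 0.213 with an SD of 0.016 between its 3 cultures.

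**Figure D3:**
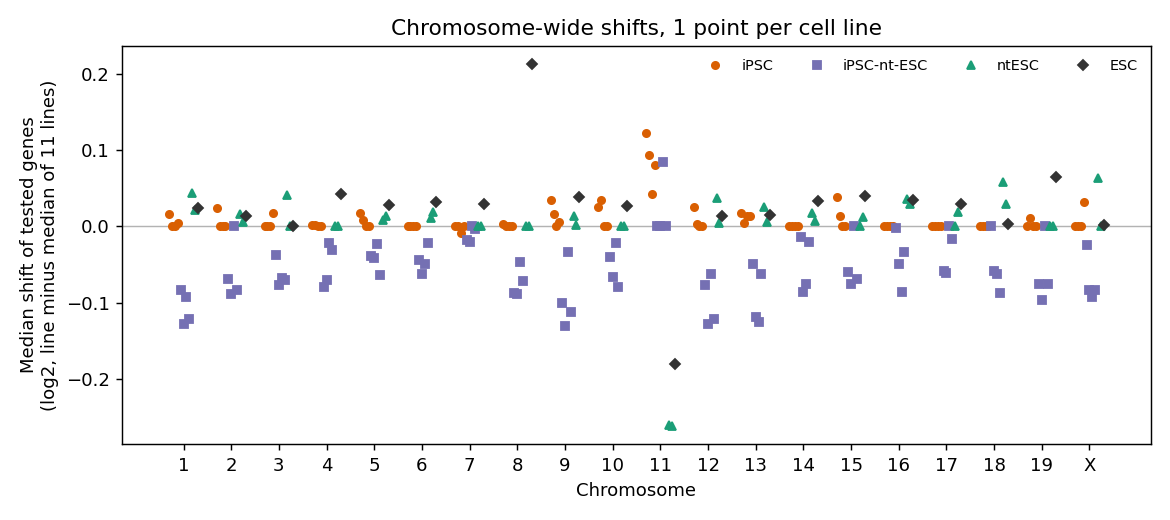
Median over the tested genes of each chromosome of a line's mean minus the median of the 11 lines (log2 units), 1 point per line. On chromosome 11 the ntESC lines (-0.261 and -0.262) and the ESC line (-0.181) lie below all 8 iPSC and iPSC-nt-ESC lines, and on chromosome 8 the ESC line lies at 0.213.

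The comparison of iPSC-nt-ESC with iPSC lines asks what a second reprogramming, in the oocyte, changed in cells already reprogrammed by factors. Pik3cd, a catalytic subunit of phosphoinositide 3-kinase, fell most, from 13.70 ± 0.03 (SD, n = 4 lines) to 8.59 ± 0.31 (n = 4), 34.6-fold (SE 0.14, adjusted p = 1.8e-08), although a pair of its other probe sets rose, by 1.38 and 1.18 log2 units. Serpinb2, an inhibitor of plasminogen activators, rose most, from 5.34 ± 0.09 (n = 4) to 9.66 ± 0.59 (n = 4), 19.9-fold (SE 0.24, adjusted p = 2.1e-06). Myc rose 5.95-fold (SE 0.49, adjusted p = 0.0018), with 9.58 ± 1.21 (n = 4) against 7.01 ± 0.42 (n = 4). The pluripotency gene Utf1 rose 4.4-fold (12.50 ± 0.10 against 10.36 ± 0.23, n = 4 each; adjusted p = 4e-06).

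Other genes that rose were the zinc finger gene Rex2 (7.45-fold), Spry4 (7.07-fold), the protease inhibitor gene Tfpi2 (7.03-fold), the lipase gene Pla2g7 (6.89-fold), the membrane protein gene Tm4sf1 (6.5-fold), the cell cycle factor gene E2f4 (6.42-fold), the interferon-induced GTPase gene Irgm1 (6.35-fold) and the thyrotropin-releasing hormone gene Trh (6.14-fold), with adjusted p between 4.6e-08 and 0.0012. Genes that fell were the heat shock factor gene Hsf2 (11.1-fold), the glycogen regulator Ppp1r3c (9.07-fold), the transporter gene Slc16a6 (6.48-fold), Ccdc172 (5.83-fold), the meiosis regulator Marf1 (5.72-fold), Anp32a (5.7-fold), the kinesin gene Kif26a (5.6-fold), the noncoding Zfas1 (5.5-fold) and the receptor gene Adgrb2 (5.21-fold), with adjusted p between 4.6e-08 and 0.0015. In each of these, the 4 lines of one type lay above all 4 of the other, which the rule for naming them required. Other probe sets of Marf1 changed by -0.28 (adjusted p = 0.24) and -0.57 (adjusted p = 0.047).

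Cell cycle genes moved up (camera adjusted p = 0.012; adjusted p = 0.28 with an estimated correlation), with 14 rising, 4 falling and 15 not past of 33, and 15 and 4 adjusted over the list alone. The inhibitor genes Cdkn2a (-2.34 log2 units, SE 0.19, adjusted p = 1.7e-05) and Cdkn1b (-1.41, SE 0.17, adjusted p = 0.00016) fell. Fibroblast markers moved up as well (camera adjusted p = 0.0072; adjusted p = 0.55 with an estimated correlation), with 19 rising, 9 falling and 13 not past of 41, the same counts adjusted over the list alone. The matrix protease Mmp3 rose by 1.94 (adjusted p = 4.2e-05) and Col1a1 by 1.57 (adjusted p = 0.00019), while another probe set of Col1a1 fell by 0.93. With the line number as a block, in a fit of both types alone, both lists kept a camera adjusted p of 0.0095. Interferon response genes were called up there at 0.035, against 0.092 in the main fit of all 11 lines. The block and the lines fitted changed together, so the interferon call cannot be credited to the block. In the main fit 5 of 17 interferon genes rose, 3 fell and 9 did not pass (5 and 2 adjusted over the list alone). With an estimated correlation, which was not run with the block, the camera adjusted p of the interferon list was 0.28 in the main fit.

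Of 36 core pluripotency genes 17 rose, 9 fell and 10 did not pass, with 17 and 9 adjusted over the list alone (camera adjusted p = 0.097). The Nodal inhibitor Lefty1 rose by 1.67 (adjusted p = 2e-04) and Pou5f1 by 0.3 (SE 0.1, adjusted p = 0.026). Nanog fell by 0.44 (SE 0.14, adjusted p = 0.027) and Klf4 by 0.55 (SE 0.19, adjusted p = 0.036), both with overlapping lines. Another probe set of Klf4 fell by 1.6 (adjusted p = 0.00018), at 1380 to 3043 against 4690 to 6214 in iPSC lines. Sox2 changed by -0.07 (adjusted p = 0.65). The maintenance DNA methyltransferase gene Dnmt1 fell by 1.32 (adjusted p = 2.6e-05) and the de novo enzyme gene Dnmt3b rose by 0.96 (adjusted p = 0.0022). Another probe set of Dnmt3b changed by -0.46 (adjusted p = 0.14). Among imprinted genes the growth factor gene Igf2 rose by 0.77 (adjusted p = 0.00065), Nnat by 1.52 (adjusted p = 0.00013) and Dlk1 by 0.76 (adjusted p = 0.0029). Mirg rose by 0.9 with overlapping lines (adjusted p = 0.018). Sfmbt2 fell by 2.05 (adjusted p = 3.7e-05), while another of its probe sets changed by -0.14 (adjusted p = 0.73). Meg3 fell by 1 (adjusted p = 0.00023), while another of its probe sets rose by 0.46. In the germ line list, not called, the meiotic RNA-binding gene Dazl fell by 2.14 (adjusted p = 6e-04) and Asz1 by 1.36 (adjusted p = 0.00096). Another probe set of Asz1 changed by -0.56 (adjusted p = 0.07). Bmp4, a mesoderm inducer, rose by 2.06 (adjusted p = 0.00024), and Eif2s3y stayed low in both types (-0.35, adjusted p = 0.45).

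In all, 6048 of 12080 genes (50.1%) differed, 2213 higher and 3835 lower in iPSC-nt-ESC lines, 283 and 650 of them by at least 2-fold, around a median change of -0.104 over all genes. Array prefix and type cannot be told apart here, and of 2774 further probe sets called for the same genes 793 (28.6%) had the opposite sign, against 0 of 226 between iPSC and ntESC lines. Calls of Pou5f1, Klf4, Nanog and Mirg ended when single lines were left out, those of Pou5f1, Klf4 and Mirg also with the line number as a block, those of Col1a1 and Dnmt3b with the mean of all probe sets, and those of Pou5f1 and the cell cycle list with quantile normalisation.

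The comparison of iPSC-nt-ESC with ntESC lines asks whether lines that had both passed through an oocyte still differed with the nucleus they started from, an iPSC or a fibroblast. Eif2s3y was 76.7-fold lower in iPSC-nt-ESC lines (5.44 ± 0.22, SD, n = 4, against 11.70 ± 0.14, n = 2; SE 0.45, adjusted p = 1.6e-05), and Uty (13-fold) and Uba1y (11.9-fold) were lower too. Usp17la fell 8.61-fold (SE 0.34, adjusted p = 0.00014), Sp110 6.95-fold (adjusted p = 0.00017), Zfp352 6.21-fold (adjusted p = 3e-04) and Tcstv1 4.47-fold (adjusted p = 8.7e-05). Serpinb2 was higher (10.6-fold, SE 0.29, adjusted p = 3.2e-05), as were interferon-induced GTPase genes, Gbp2b (10.4-fold), Gbp2 (8.32-fold) and Irgm1 (7.7-fold).

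Further genes that rose were Ipp (9.34-fold), the X-linked deubiquitinase gene Usp26 (8.96-fold), the lactate transporter gene Slc16a3 (8.21-fold), Sdr39u1 (7.54-fold), Abhd15 (6.35-fold) and Rex2 (6.29-fold), with adjusted p between 3.9e-06 and 0.00065. Pik3cd (37-fold), Hsf2 (12-fold), Anp32a (6.71-fold) and the ciliary gene Ahi1 (6.33-fold) fell, with adjusted p between 1.2e-07 and 5.6e-05. Another probe set of Ahi1 rose by 0.94 log2 units, and a pair of further probe sets of Pik3cd by 2.03 and 1.35. Interferon response genes moved up (camera adjusted p = 0.046; adjusted p = 0.19 with an estimated correlation), with 5 rising, 2 falling and 10 not past of 17, and 6 and 2 adjusted over the list alone. Stat2, which transmits the interferon signal, rose by 1.3 (adjusted p = 0.0012), while another of its probe sets changed by -0.03 (adjusted p = 0.9). Genes of the primitive streak and mesoderm moved up (camera adjusted p = 0.046; adjusted p = 0.19 with an estimated correlation), with 6 rising, none falling and 7 not past of 13, and 7 adjusted over the list alone. Fgf17 rose by 1.44 (adjusted p = 0.00029) and the mesoderm factor gene Msgn1 by 1.16 (adjusted p = 0.011). In the 2-cell-like list 7 of 12 genes fell and none rose, the same adjusted over the list alone, and in the sex chromosome list 2 of 3 fell (2 adjusted over the list alone), but neither list passed (camera adjusted p = 0.05 each; 0.61 and 0.43 with an estimated correlation).

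Imprinted Mest rose by 1.57 (adjusted p = 5.2e-05) and Dlk1 by 1.36 (adjusted p = 0.00055), and Utf1 rose 4.01-fold (adjusted p = 2.6e-05). Meg3 fell by 0.49 (adjusted p = 0.034), while 3 other probe sets rose, by 1.26, 0.64 and 0.71, and Nanog fell by 0.52 (adjusted p = 0.039) with overlapping lines. In all, 4648 genes (38.5%) differed, 1758 higher and 2890 lower (2263 and 2304 with the mean of all probe sets), 406 and 554 by at least 2-fold, around a median change of -0.091. Of 1964 further called probe sets 689 (35.1%) had the opposite sign, and the count fell to 2524 without ntESC-1 and 2832 without ntESC-2. Single lines left out ended the calls of Meg3, Nanog and Msgn1 and of both lists called up, and so did quantile normalisation for those lists and the mean of all probe sets for Pik3cd.

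The comparisons with the ESC line ask how far each kind of reprogrammed line lay from cells derived from an embryo. E14 also differs in strain label from all other lines, so strain and origin cannot be told apart in these comparisons. Each of them rests on 1 ESC line, so the spread between ESC lines was assumed and not measured. Mid1, an X-linked ubiquitin ligase gene, separated E14 from all other lines: it stood at 10.7 in ESC and at 4.89 ± 0.23 (SD, n = 4) in iPSC lines, 56.3-fold lower (SE 0.3, adjusted p = 1.5e-05). Also lower in iPSC lines were Tcstv3, a gene active in 2-cell embryos, 19.9-fold (SE 0.29, adjusted p = 0.00011), Tcstv1 10.9-fold (adjusted p = 0.00019), the arginase gene Arg2 8.71-fold (adjusted p = 0.0011) and Usp17la 7.67-fold (adjusted p = 0.0066). The Y-linked Eif2s3y (56.4-fold), Uba1y (20.3-fold) and Uty (12.4-fold) were lower in iPSC lines, whereas Scml2 was 18.8-fold higher (SE 0.51, adjusted p = 0.002). Pou5f1 (-0.35, adjusted p = 0.24) and Nanog (0.09, adjusted p = 0.88) did not pass.

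Also higher in iPSC lines than in ESC were Ipp (13.5-fold), the imprinted noncoding Snhg14 (11.4-fold), Elobl (10.5-fold), Tnfsf13os (9.84-fold), Nxf3 (9.15-fold), Fank1 (4.96-fold), the glutamate receptor gene Grm7 (4.89-fold), Lama3 (4.87-fold) and Lrrc23 (4.59-fold), with adjusted p between 0.00014 and 0.022. Pramel18 (10.3-fold), Serpinb2 (8.63-fold) and Ubtfl1 (7.9-fold) were lower, as were Phlda2 (3.66-fold, adjusted p = 0.0073), Igf2 (1.79-fold, adjusted p = 0.035) and Xist (1.74-fold, adjusted p = 0.022). The 2-cell-like list moved down (camera adjusted p = 2.6e-07; adjusted p = 0.21 with an estimated correlation), with 6 of 12 falling, none rising and 7 falling adjusted over the list alone. Fibroblast markers moved down (camera adjusted p = 6.1e-11; adjusted p = 0.19 with an estimated correlation), with 10 of 41 falling, none rising and 20 falling adjusted over the list alone, among them S100a6 (-1.29, adjusted p = 0.0077) and Mmp3 (-1.2, adjusted p = 0.041). Cholesterol synthesis genes moved up (camera adjusted p = 0.0085; adjusted p = 0.27 with an estimated correlation); Fdps alone of 18 rose (0.61, adjusted p = 0.049), and 5 adjusted over the list alone. Germ line genes moved up (camera adjusted p = 0.046; adjusted p = 0.47 with an estimated correlation), with 4 of 24 rising, including Brdt (2.19, adjusted p = 0.0044), and 6 rising and 1 falling adjusted over the list alone. All 3 sex chromosome genes fell (camera adjusted p = 2.5e-06; adjusted p = 0.07 with an estimated correlation; 3 adjusted over the list alone).

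Between iPSC lines and ESC 630 genes (5.22%) differed, 301 higher and 329 lower (396 and 284 with quantile normalisation), 126 and 160 by at least 2-fold. The count fell to 338 without iPSC-2, 383 without iPSC-3, 379 without iPSC-4 and 418 without chromosomes 11 and Y (152 higher and 266 lower). Single lines left out ended the calls of Elobl, Xist, Igf2, Mmp3, Fdps and the germ line list, quantile normalisation those of Mmp3 and the germ line list, and the mean of all probe sets that of Snhg14. Another probe set of Brdt changed by 0.88 log2 units. The ESC value rests on 1 line. On chromosome 8, which stood higher in that line, the median change in iPSC lines was -0.21 against -0.01 on other chromosomes. Against ESC it was -0.21 against -0.03 in ntESC lines and -0.3 against -0.12 in iPSC-nt-ESC lines.

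Against ESC the ntESC lines differed in 40 genes (0.331%), 20 higher and 20 lower (42 and 19 with quantile normalisation), and 20 and 16 of the 40 by at least 2-fold. Mid1 was 55.7-fold lower (SE 0.32, adjusted p = 3.9e-05), Tcstv3 10.8-fold lower (adjusted p = 0.00091) and Tcstv1 4.19-fold lower (adjusted p = 0.023). The epidermal gene Krtdap (8.93-fold), the chemokine gene Ccl3 (4.17-fold), Pla2g7 (3.11-fold), the interferon-induced gene Ifit2 (2.84-fold), Unc13b (2.45-fold), Nosip (2.45-fold) and Gpr182 (2.41-fold) were lower as well. Snhg14 was 13.8-fold higher (SE 0.47, adjusted p = 0.0084), Tnfsf13os 12.1-fold, Lrrc23 6.64-fold, Grm7 5.32-fold, the endoplasmic reticulum chaperone gene Calr3 5.03-fold, the ribonuclease genes Ang 4.94-fold and Rnase4 4.93-fold, the amino acid transporter gene Slc1a5 3.87-fold, Dtd2 3.72-fold and Amacr 3.71-fold. Eif2s3y (0.1, adjusted p = 0.96), Pou5f1 (-0.16, adjusted p = 0.72) and Nanog (0.17, adjusted p = 0.79) did not pass.

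The 2-cell-like list moved down in ntESC lines (camera adjusted p = 1.2e-05; adjusted p = 0.36 with an estimated correlation), with 2 of 12 falling, none rising and 4 falling adjusted over the list alone. For 4 other lists camera gave a call while limma called 0 members over all genes: fibroblast markers (41, down, camera adjusted p = 0.00038), amino acid and endoplasmic reticulum stress (29, up, 0.0078), cholesterol synthesis (18, up, 0.017) and trophoblast (19, down, 0.017). With an estimated correlation their adjusted p were 0.47, 0.36, 0.36 and 0.52, and adjusted over the list alone 4 trophoblast genes fell and 0 genes of the other lists passed, in a comparison where 1507 of all genes had an unadjusted p under 0.05. Without ntESC-2 the count was 23, and leaving out 1 ntESC line ended the calls of Lrrc23, Grm7, Dtd2, Krtdap, Tcstv1, Ccl3, Pla2g7, Ifit2, Unc13b, Nosip, Gpr182 and the trophoblast list. Quantile normalisation ended the calls of the stress and cholesterol lists, Ccl3 and Ifit2, and the mean of all probe sets those of Snhg14, Slc1a5, Unc13b and Nosip. Other probe sets of Calr3 changed by 0.37 and 0.65 log2 units.

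Against ESC genes lower in the iPSC-nt-ESC lines included Tcstv3 31.1-fold (SE 0.29, adjusted p = 1.1e-05), Usp17la 22.6-fold (SE 0.44, adjusted p = 0.00023), Tcstv1 18.7-fold (adjusted p = 1.8e-05), Arg2 13.2-fold (adjusted p = 0.00014) and Ubtfl1 12.1-fold (adjusted p = 0.001). Eif2s3y (71.6-fold), Mid1 (41.2-fold), Pik3cd (37-fold), Uba1y (16.3-fold) and Uty (12-fold) were lower too, with other probe sets of Pik3cd higher by 1.61 and 1.07 log2 units. Elobl (21-fold, SE 0.7, adjusted p = 0.0021), Snhg14 (17.7-fold), Ipp (15.8-fold), Tnfsf13os (8.89-fold), Usp26 (8.2-fold), Slc16a3 (6.42-fold), Abhd15 (6.24-fold), Irgm1 (6.19-fold), Rex2 (5.89-fold) and Nxf3 (5.85-fold) were higher. The 2-cell-like list moved down (camera adjusted p = 0.00024; adjusted p = 0.39 with an estimated correlation; 7 of 12 fell, 7 adjusted over the list alone). The interferon list moved up (camera adjusted p = 0.047; adjusted p = 0.28 with an estimated correlation; 3 of 17 rose and 1 fell, 5 and 1 adjusted over the list alone). The sex chromosome list moved down (camera adjusted p = 0.011; adjusted p = 0.28 with an estimated correlation; 2 of 3 fell, 3 adjusted over the list alone).

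Between iPSC-nt-ESC lines and ESC 3150 genes (26.1%) differed, 1036 higher and 2114 lower, 305 and 760 by at least 2-fold, around a median of -0.129. Prefix and type cannot be told apart, 245 of 1054 further called probe sets (23.2%) had the opposite sign, and without iPSC-nt-ESC-3 the count was 4833 and the interferon and sex chromosome lists lost their calls. Of the 16 genes fixed by name 13 were tested; from iPSC to iPSC-nt-ESC lines 9 passed and the others changed by -0.54 to -0.07, while between ntESC and ESC none passed, with changes of -0.99 to 0.17.

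The distance of each line to ESC, as 1 minus the correlation across genes, averaged 0.0301 ± 0.00225 (SD, n = 4) for iPSC, 0.0522 ± 0.00164 (n = 4) for iPSC-nt-ESC and 0.02 ± 0.000483 (n = 2) for ntESC lines. The iPSC lines were farther than the ntESC lines by 0.0101, with all 4 beyond both, and by 0.00376 without the filter (exact two-sided permutation p = 0.067, the smallest that 15 splits allow). The iPSC-nt-ESC lines were farther than the iPSC lines by 0.0222, with all 4 beyond all 4, and by 0.0114 without the filter (exact two-sided permutation p = 0.029, the smallest that 70 assignments allow). These assignments ignore that each iPSC-nt-ESC line is paired with its own iPSC line. Exchanges within the pairs could not give so small a p. Array prefix and type cannot be told apart in the difference between iPSC-nt-ESC and iPSC lines. Each distance also holds the difference in strain label between E14 and the other lines.

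Whether nuclear transfer turned back the differences of iPSC from ntESC lines was asked gene by gene. Of the 580 genes higher in iPSC lines, 269 were called lower after transfer and 68 still higher; Ccdc172 was among those that fell. Of the 276 lower genes, 97 were called higher after transfer and 59 still lower; Spry4 was among those that rose. Independent lists would share 184 and 50.6 genes in the opposite directions, but these contrasts share the iPSC lines with opposite sign. Those counts are therefore not the values for unchanged groups, which were not simulated for called genes. In all, 66.1% of the 856 genes had the opposite sign. In 100 simulations of unchanged groups that share the iPSC lines it was 63.4%, but over all genes and not among called ones. The simulated share is therefore not the chance value for the 856 genes. With the iPSC lines split so that the contrasts shared none, the share among called genes was 61.7% on average (59% to 66.7%). The correlation of the changes across genes was -0.29, against -0.41 simulated and -0.24 with split lines, and the covariance was -0.0624, against -0.0145 simulated, a difference of -0.0479. Genes are not independent replicates, and the second contrast carries the array prefix.

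The lines of a type were compared to ask how alike they were. Among the 4 iPSC lines the LIF feedback inhibitor Socs3 had a signal of 8002 ± 308 and 7441 ± 327 in lines 1 and 2 and of 1981 ± 441 and 2597 ± 106 in lines 3 and 4 (SD, n = 3 cultures each; 4.08-fold range, adjusted p = 1.2e-05). Lines 1 and 2 share 1 name stem and lines 3 and 4 another, so the 4 lines may not be independent replicates. The early response gene Ier3 divided the lines the same way (4907 ± 106, 4294 ± 277, 1298 ± 159 and 1402 ± 197; adjusted p = 9.4e-06), as did Ppp1r3c (3.69-fold range, adjusted p = 0.00019) and Gdap10 (3.38-fold, adjusted p = 0.00028). Spry4 had the widest range, 4.93-fold, and was higher in lines 3 and 4 (231.9 ± 37.5 and 195.3 ± 37.1) than in lines 1 and 2 (45.94 ± 14 and 38.51 ± 11.8; adjusted p = 0.00012). Eif2s3y was 121.8 ± 12.7 in iPSC-3 and between 22.65 and 47.3 in the others (adjusted p = 9.6e-05), against 3551 ± 359 and 3096 ± 159 in the ntESC lines. The homeobox gene Barx1 (4.22-fold), Golga7b (4.15-fold), Slc16a14 (3.67-fold) and Mzf1 (3.31-fold) also varied, while Pou5f1 (adjusted p = 0.81) and Nanog (adjusted p = 0.4) did not pass. In all, 3877 genes (32.1%) differed among the iPSC lines, 153 with a range of at least 2-fold, and leaving out 1 culture number left 890 to 1381.

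Among the iPSC-nt-ESC lines, line 3 stood apart for most of the genes with the widest ranges. Igsf23 was 4768 ± 185 there and 383.5 to 410 in the others (SD, n = 3 cultures; 12.2-fold, adjusted p = 1e-06), and the peptide hormone gene Adm 2497 ± 171 against 312.7 to 408 (7.73-fold, adjusted p = 1.6e-06). The homeobox gene Gbx2 stood there at 70.12 ± 3.22 against 453.1 to 722.1 (8.97-fold, adjusted p = 1e-06), Pramel7 at 24.6 ± 16.1 against 231.7 to 357.8 (11.1-fold, adjusted p = 4.6e-05) and Pramel6 at 30.12 ± 7.12 against 188.2 to 285.6 (7.06-fold, adjusted p = 1.2e-05). Myc was 223.4 ± 94.6 in line 3 and 940.6 to 1290 in the others (adjusted p = 5.9e-05), whereas Klf4 was higher in line 3 (10860 ± 563 against 5579 to 7154; adjusted p = 0.00085). The imprinted Mirg was lower in it (278 ± 67.9 against 547.9 to 697.5; adjusted p = 0.00039), and Nanog was higher in line 4 (13600 ± 570 against 8821 to 9088; adjusted p = 0.0042). Aspa (7.19-fold), Apol6 (6.75-fold) and Mep1b (6.05-fold) were lowest in line 3 and Spata21 (6.43-fold) highest in it, and the sulfotransferase gene Chst15 was low in line 4 (10.98 ± 4.2; 7.55-fold). Line 3 correlated with the other lines at 0.969 to 0.9742, and these with each other at 0.9907 to 0.9948. In all, 5511 genes (45.6%) differed, 923 by at least 2-fold, with 1806 without culture 1 and 2212 without culture 2.

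Between the 2 ntESC lines Olig2, an oligodendrocyte factor, had the widest range of the named genes, and the neighbouring Olig1 differed too. Olig2 was 4.141 ± 5 in line 1 and 175.9 ± 35.7 in line 2 (SD, n = 3 cultures each; 12.3-fold, adjusted p = 0.0024), and Olig1 71.19 ± 18 and 400.8 ± 26.4 (5.07-fold, adjusted p = 0.0029). Guca1b (5.72-fold), Mgl2 (5.34-fold), Trim34a (5.32-fold), the ubiquitin-like Ubd (4.77-fold), Trim12a (4.32-fold), Efhc2 (4.19-fold) and the signalling adaptor gene Grb14 (3.86-fold) were also higher in line 2, and the ciliary gene Drc1 (4.38-fold) in line 1. Meg3 was 4539 ± 161 in line 1 and 6267 ± 338 in line 2 (adjusted p = 0.016). In all, 941 genes (7.79%) differed, 92 by at least 2-fold, but 29, 20 and 13 genes were called without culture 1, 2 or 3.

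Whether an iPSC-nt-ESC line kept traits of its own parent line was asked from the deviations of each line from its type mean. Over the 12080 genes, the 4 pairs had a mean correlation of -0.015, and 24 assignments of daughters to parents reached up to 0.196 (exact one-sided permutation p = 0.54). The named daughter was the best match of 1 of 4 parents, and the named parent that of 1 of 4 daughters. Without the pair of line 3, left out after seeing the data, the mean was 0.176 (exact one-sided permutation p = 0.17, the smallest that 3 pairs allow).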

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

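For chromosome 11, the tests of whole-array scaling, of parts of the chromosome and of the array prefix were chosen after the results were seen. The tests for the iPSC-nt-ESC arrays were not. The rule for an extra copy was set before its test was run, but for a chromosome picked out by these results.

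In 165 sets of 4 lines the lowest or highest value was compared with the nearest other (Dixon's test), which by chance marks about 1 in 20. It marked 17 values, 8 of them in iPSC-nt-ESC-3. In that line the glycogen regulator Ppp1r3c stood at 6.06 log2 units (4.28 to 4.32 in the other iPSC-nt-ESC lines), the hypoxia-induced repressor Bhlhe40 at 10.25 (8.6 to 8.71), the cell cycle inhibitor Cdkn1b at 9.2 (8.38 to 8.49) and the imprinted Nnat at 9.25 (8.38 to 8.51). The collagen gene Col1a1 stood there at 9.5 (10.36 to 10.46), the growth factor gene Igf2 at 9.81 (10.3 to 10.35) and Elobl at 9.5 (11.64 to 11.89). In iPSC-nt-ESC-4 Nanog stood at 13.73 (13.11 to 13.14). In iPSC-nt-ESC-1 the Y-linked Uba1y stood at 4.6 (5.27 to 5.37) and Mid1 at 4.75 (5.47 to 5.57). Among iPSC lines the cell cycle inhibitor gene Cdkn2a was 8.68 in iPSC-4 (9.45 to 9.6), Tm4sf1 6.27 in iPSC-2 (6.83 to 6.89) and Dlk1 6.13 in iPSC-3 (6.51 to 6.57).

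Shifts of whole chromosomes against the median of 11 lines were marked in 4 lines. That median fixes lines in the middle at 0, so the test decides nothing for 3 of them, where the other lines stand at 0. The chromosome 8 shift of iPSC-1 was 0.003 (0 in the other iPSC lines), the chromosome X shift of iPSC-4 was 0.032 (0 in the others) and that of iPSC-nt-ESC-1 was -0.025 (-0.093 to -0.083). The chromosome 11 shift of iPSC-nt-ESC-3 was 0.085 (0 in the others).

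The higher signal of chromosome 11 genes in iPSC than in ntESC lines may come from copy number. The difference from other autosomes was 0.45 after quantile normalisation and 0.44 within 1 array prefix, and the 10 parts of the chromosome had medians from 0.32 to 0.47, so scaling, prefix or a single region do not account for it. Among its strongest genes, where background lowers folds least, the difference in the 8 lines lay between 0.45 and 0.51. This lies within the range of 0.2 to 0.7 set before the test for an extra copy and below the 0.6 of 3 copies against 2. For all chromosome 11 genes the difference in the 8 lines was 0.43 to 0.48 and already lay in that range. This part of the rule could therefore hardly fail. At 2 decimals the difference of the strongest genes was at or above that of all chromosome 11 genes in each line. Unrounded it was lower in iPSC-2, so by the rule an extra copy stayed undecided, by less than the printed precision. Loss of a copy in the ntESC and ESC lines was not tested, and a count of chromosomes would decide.

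The transferrin receptor control averaged 2403 on iPSC-nt-ESC arrays (361.6 for ESC). Of its gene Tfrc, the brightest probe set did not follow, at 12650 to 15150 in iPSC-nt-ESC and 14340 to 16050 in iPSC lines, while the others stood at 5060 to 7024 against 589.2 to 669.9 and at 1904 to 2700 against 266.9 to 575.9.

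Different labelling or hybridisation of these arrays may make part of the 6048 genes called between iPSC-nt-ESC and iPSC lines: 28.6% of further called probe sets had the opposite sign to their gene, against 0% between iPSC and ntESC lines. The 0% rests on 226 probe sets, against 2774 here, and any share would exceed it. The test therefore cannot tell how large that part is. Whole-array scaling does not account for the 6048 calls, since 5986 genes were called after quantile normalisation. Of 35 splits of the 8 lines 1, the real one, reached the count and the highest other gave 0. These splits ignore that each iPSC-nt-ESC line is paired with its own iPSC line. Exchanges within the pairs alone are too few to exclude chance. Biology and array set stay mixed, and iPSC lines hybridised again beside iPSC-nt-ESC lines would part them.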

How the results depend on the processing

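The fits without chromosomes 8, 11 or Y and the test without the pair of line 3 were chosen after the results were seen; the other alternatives were chosen before the data were examined. Unless stated, the cause of a move was not tested. Folds of at least 2 keep fewer genes, all probe sets or arrays as independent replicates give more tests or degrees of freedom, and these moves follow from construction.

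For iPSC against ntESC lines (856 genes) no filter gave 493, all probe sets 1855, arrays with the line as a random block 2141, the same with the culture number as a further block 2064, independent arrays 4867, a fit of both types alone 1599, genes without chromosomes 11 and Y 417 and folds of at least 2 183. Leaving out 1 line gave 167 to 826. With the M1 or M2 name stem as a block and ESC left out, 885 genes were called. The same fit called 6133 between iPSC-nt-ESC and iPSC lines and 4709 between iPSC-nt-ESC and ntESC lines. For iPSC-nt-ESC against iPSC lines (6048) all probe sets gave 12336, folds of at least 2 933 and 1 line left out 4960 to 7281. The line number as a block, in a fit of both types alone, gave 5258, and that fit without the block gave 5813. Lists called rose from 2 in the main fit to 3 with the block and both types alone. For iPSC-nt-ESC against ntESC lines (4648) all probe sets gave 10069 (4997 higher and 5072 lower), independent arrays 7598, folds of at least 2 960 and 1 line left out 2524 to 6006; with the mean of probe sets 2263 were higher and 2304 lower.

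For iPSC lines against ESC (630) no filter gave 376, arrays with the line as a random block 1268, the same with the culture number 1250, independent arrays 3568, both types alone 1184, genes without chromosomes 11 and Y 418, folds of at least 2 286 and 1 line left out 338 to 426. For ntESC lines against ESC (40) quantile normalisation gave 61, no filter 26, all probe sets 125, arrays with the line as a random block 277, the same with the culture number 261, independent arrays 2515 and 1 line left out 23 to 40. For iPSC-nt-ESC lines against ESC (3150) all probe sets gave 6933, independent arrays 6604, both types alone 1162, folds of at least 2 1065 and 1 line left out 2580 to 4833.

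Among iPSC lines (3877 genes) 153 had a range of at least 2-fold, and 1 culture number left out gave 890 to 1381. Among iPSC-nt-ESC lines (5511) these were 923 and 1806 to 4171. Between ntESC lines (941) they were 92 and 13 to 29, while no filter gave 263, the culture number as a block 100 and all 33 arrays in 1 fit 1428. Culture numbers tie arrays of different lines by number only: their mean correlation was -0.002 within a number and 0.001 across numbers, and 12 of 33 arrays matched their own number best.

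Of 21 list calls 0 held with an estimated correlation, and 17 to 26 were called with 1 line left out. Fry, which does not set a list against the other genes, called 35, and fry on arrays 69. The mean chromosome 11 shift of iPSC lines minus that of ntESC lines, 0.346, was 0.312 after quantile normalisation. The parent and daughter correlation of -0.015 turned to 0.176 without the pair of line 3. The difference in distance to ESC between iPSC and ntESC lines, 0.0101, ranged from 0.00376 without the filter to 0.0112, and that between iPSC-nt-ESC and iPSC lines, 0.0222, from 0.0114 without the filter to 0.0246. Their exact p was the smallest the splits allow each time and cannot show stability. The return of 66.1% was 64% to 67.5% in 3 alternatives, for which values without change were not simulated.

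Of 186 results of named genes, quantile normalisation kept 179 and weakened 6, no filter kept 169 and weakened 17, no offset kept 176, and the mean of probe sets kept 175 and weakened 9. Of 1014 results with 1 line left out 905 stayed and 106 weakened. Nanog in iPSC against ntESC lines ranged from -0.22 to 0.06, turning without ntESC-2, and Eif2s3y in iPSC-nt-ESC against iPSC lines from -0.58 to 0.08, turning without iPSC-3; neither was called. Meg3 in iPSC-nt-ESC against ntESC lines was 0.1 with the mean of probe sets, by construction, since its probe sets differ in sign.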

Other observations

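The tests for Y-linked genes given here were chosen after the results were seen; the counts over other splits were planned.

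Between iPSC-nt-ESC and iPSC lines 50.1% of all tested genes were called, so the counts in lists without a call describe single genes. Of 32 hypoxia and glycolysis genes 14 fell, 4 rose and 14 did not pass; the glycolytic activator gene Pfkfb3 fell by 2.09 log2 units (adjusted p = 0.001) and Bhlhe40 by 1.84 (adjusted p = 0.0049) with overlapping lines. Of 16 genes of the primitive and visceral endoderm 9 fell and 1 rose, with the basement membrane gene Col4a1 down by 1.17 (adjusted p = 5e-04). Another probe set of Col4a1 changed by -0.27 (adjusted p = 0.086). Of 34 regulators of DNA methylation and chromatin 9 rose and 14 fell, of 19 epiblast and neural genes 3 rose and 9 fell, of 24 p53 targets 3 rose and 8 fell, and of 13 heat shock genes 6 rose and 3 fell. In this comparison 28.6% of further called probe sets had the opposite sign.

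Over all 6 comparisons, 10 of the 20 lists had no call in any. Their smallest camera adjusted p were 0.061 for chromatin regulators (34 genes), 0.097 for core pluripotency (36), 0.15 for the Dlk1-Dio3 region (4), 0.16 for heat shock (13), 0.17 for other imprinted genes (35), 0.23 for primitive and visceral endoderm (16), 0.25 for epiblast and neural ectoderm (19), 0.26 for hypoxia and glycolysis (32), 0.42 for the reprogramming factors (4) and 0.72 for p53 targets (24).

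Low signal of Y-linked genes in all 8 iPSC and iPSC-nt-ESC lines, which were labelled male, may reflect loss of the Y chromosome. All 5 probe sets with signal in ntESC lines were lower in all 8 lines, by at least -2.18 log2 units, so the failure of single probe sets does not explain it. Nor does the array prefix explain it in iPSC lines, since Eif2s3y differed by -5.92 between iPSC and ntESC lines within 1 prefix. Female cells with both X chromosomes active do not explain it in iPSC lines either. Between iPSC and ntESC lines the X median minus that of other autosomes was -0.01, and Xist changed by -0.36. Both tests leave out the iPSC-nt-ESC lines, which have the other prefix. These values cannot exclude female cells with a single X chromosome. In iPSC-3 Eif2s3y kept a signal of 121.8 ± 12.7 (SD, n = 3 cultures), against 22.65 to 47.3 in the other iPSC lines, so whether every cell of that line had lost it stays open, as does the state of the donor fibroblasts.

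Among other splits of the same lines, the real one alone reached its count in each test. Between iPSC and ntESC lines it was 1 of 15 (856 genes; highest other 242, for iPSC-3 and iPSC-4 with both ntESC lines against iPSC-1 and iPSC-2), too few splits to exclude chance. Between iPSC-nt-ESC and ntESC lines it was 1 of 15 (4648; highest other 0), again too few. Among cultures it was 1 of 100 drawn splits for iPSC lines (3877; highest other 1), 1 of 100 for iPSC-nt-ESC lines (5511; highest other 3360) and 1 of 10 for ntESC lines (941; highest other 0), the last too few.

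Whether nuclear transfer acted differently on lines with the M1 and the M2 name stem was tested with limma. It called 0 genes, with 2062 at an unadjusted p under 0.05, 4 residual degrees of freedom and a smallest adjusted p of 0.18, for Ier3 (difference -1.92).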
